A study of Mus musculus with 3 samples.

How the data were processed

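Chromatin bound by FOG2 was mapped by biotin pulldown and sequencing in heart ventricles of mouse embryos at embryonic day 12.5. Per the labels' protocols, the mice carried a tagged FOG2 allele together with the bacterial biotin ligase BirA expressed from the Rosa26 locus, so that the tagged protein was biotinylated in the tissue. The labels also give the genotype as wild type and the antibody as FOG2, which differs from this protocol, and the protocol is followed here. About 20 ventricles made up each biological replicate. They were fixed in 1% formaldehyde for 10 minutes and sonicated, and FOG2 with its DNA was recovered on streptavidin beads. The 2 FOG2 pulldown libraries and the 1 input library were grouped by their labels.

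The values analysed were a single list of peaks deposited by the authors for the pooled FOG2 pulldown. The list had been filtered against blacklisted regions, per the deposited file's name and peak names, and 17 of the 6183 running peak numbers were missing from it. Bowtie2 2.3.2, SAMtools 1.5, Picard and MACS2 2.1.1 and the build mm10 are named in the submitters' processing notes. The settings of the aligner and the peak caller are not given in the sources used here. The deposited fold is a linear ratio of pulldown to control at the peak summit, as the authors' peak caller wrote it. The deposited −log10 p and −log10 q values are the caller's for the same summit. The deposited display score equalled the whole part of 10 times the −log10 q in all 6166 peaks and was not used further. Because the list was pooled, it held no value per replicate, and neither a spread between replicates nor a test between libraries could be computed. Peaks are not replicates, and every p-value below describes this list only.

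The number of pulldown fragments at each summit was recovered from the deposited fold and −log10 p. A Poisson tail and a fold computed with 1 added to both sides, as MACS2 does, were solved for a whole number of fragments and a control level. A whole number matched the deposited −log10 p within 0.001 in 100% of peaks, with a largest misfit of 0.000148, and in 83 peaks another whole number also lay within that tolerance. The lowest control level, 0.588, was taken as the background. The other control levels were whole multiples, within 0.0002, of what 1 input read is worth at the summit (0.608) or averaged over 1 kb (0.103) or 10 kb (0.0103), and 90.5% of all levels needed no 10 kb step. The first of these values puts the input at 1.64 reads per pulldown read. If the caller's default mouse genome size was used, which is not given in the sources used here, these values correspond to about 6.47 M pulldown and 10.6 M input fragments. Intervals on fragments are exact 95% Poisson intervals and cover counting error only. This recovery was chosen after the values were seen.

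Gene positions came from a RefSeq gene table of the mm10 assembly (GRCm38.p6), which gives the start and end of each gene but neither strand, exons nor sequence. The plan had been to measure distances to transcription start sites and to split gene bodies into exons and introns. Summits were instead placed within 1 kb of either end of a protein-coding gene, elsewhere in a gene body, or outside gene bodies. Motifs at summits, their co-occurrence and placement matched on GC content need the genome sequence and were not analysed here.

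The shares of summits in these classes were compared with 1000 random placements on the same chromosome, between its first and last annotated gene, in two-sided permutation tests. Assembly gaps were not left out. Wilson 95% intervals and leave-one-chromosome-out jackknife standard errors were computed for each share. Median folds were compared in two-sided permutation tests with 100000 resamples, adjusted by the Benjamini-Hochberg method over both comparisons. No intervals overlapped, so each kept its own summit. Each summit was assigned to the nearest of 21631 protein-coding gene bodies within 100 kb, in place of the nearest start site. For 21 gene lists holding 353 genes, all of which were matched, the number of genes with a summit was compared with 10000 random lists of the same size. The random lists were matched on decile of territory, the stretch of genome nearer to a gene than to any other within 100 kb, measured on a 1 kb grid. These two-sided permutation tests were adjusted by the Benjamini-Hochberg method over the 21 lists, and 0.05 was the threshold throughout.

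The gene lists, the tests, the threshold and the rule for named genes were fixed before the data were examined. The rule named the 10 peaks of highest fold, the 10 genes with the most summits, up to 4 genes of highest fold in each list, and 12 genes reported whether or not they had a peak. Genes named outside this rule are said to be so, and some genes under it are not reported here. The other settings tried were peaks with a −log10 q of at least 5, a fold of at least 5, the stronger 50% of peaks, merged intervals, gene ends of 5 kb, genes of any biotype, interval overlap of at least 50%, −log10 q as the strength, and 4 other ways of assigning or matching genes. Leaving out 12 peaks at Pgk1, Larp7, Hprt and the 3 widest intervals, recovered fragments as the strength, and the nearest gene end within 100 kb were added after the data were seen, as were the test of summits lying within 10 kb of each other and the splits of the atrial fibrillation and heart failure lists.

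The procedures were tested on simulated data. Fragments were recovered exactly in 100% of 987 simulated peaks. With the real 21631 genes, 3.5% of 200 unchanged lists and 90% of 20 lists given extra peaks had an unadjusted permutation p under 0.05. Each gene of the lists given extra peaks had even odds of an added summit at the middle of its body. This is a large effect, and the 90% does not give the power for smaller excesses. The unchanged lists were random draws of genes and the simulated summits were placed uniformly. Their rate therefore does not show how the test behaves for real lists or for summits that lie close together. None of 10 uniform summit sets passed the placement test, and a set with 3% of its summits moved to gene ends gave a permutation p of 0.0198. Fewer placements were drawn in this simulation than in the main test, and 0.0198 is the smallest p they can give. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.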

Results

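FOG2, the product of Zfpm2, is a zinc finger protein that binds GATA factors and modulates their activity in the developing heart. Its chromatin occupancy was measured in ventricles of mouse embryos at E12.5 (days of gestation), in 2 pulldown libraries with 1 input library as control. The series concerns how FOG2 acts on a gene network bound by TBX5 and GATA4 in the atrium, with a view to heart failure and atrial fibrillation, and the tissue profiled here was ventricle. The pooled pulldown gave 6166 peaks on 20 chromosomes, and none lay on the Y chromosome. All folds below are those of the authors' peak caller, all positions are on mm10, and no value has a replicate spread because the replicates were pooled.

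The median peak was 251 bp wide and 6.39-fold over control, with quartiles of 5.41 and 8.66. In all, 1039 peaks (16.9%) reached 10-fold, 182 reached 20-fold and 14 reached 50-fold. A median summit rested on 12 pulldown fragments (95% Poisson interval 6.2 to 21.0), and 39.4% of summits rested on 10 or fewer. Folds of single peaks near the median therefore carried wide counting error and could not be ranked against each other. Summits lay close together, with 18.6% having another within 10 kb against a mean of 4.88% and a highest value of 6.16% in random placements (permutation p = 0.002, the smallest possible).

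The highest folds were at Pgk1 and Larp7. The peak at Pgk1, a glycolytic enzyme gene, spanned X 106186598 to 106187341, across an end of the gene body with its summit 0.15 kb outside, and was 157.8-fold over control, with 258 fragments (227 to 291). Larp7, which encodes a protein that binds the 7SK RNA, held 5 of the 10 strongest peaks, at 141-, 119-, 75.4-, 75.3- and 60.4-fold. The strongest of them spanned 127545716 to 127546525 on chromosome 3. Control levels at the Pgk1 peak and at the strongest Larp7 peak were 0.641 and 0.608, close to the background of 0.588. The remaining peaks among the strongest 10 were nearest to Arid1b (69.6-fold, 368 kb away), Csnk1g3 (68.8-fold, 342 kb away), Ank (58.5-fold, 220 kb away) and Ttc32 (56.3-fold, overlapping the gene body with its summit 0.219 kb outside).

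The 10 genes with the most summits had between 9 and 13. Macrod2 had 13 summits, Robo1, an axon guidance receptor gene, had 12, and Ror1, Ryr2, Tenm3 and Sorbs2 had 10 each. Pcdh7, Ank3, Rbfox1 and Auts2 had 9 each. Macrod2 spans 1998 kb, and its territory alone would hold 4.98 summits at the genome-wide density. The territory of Ryr2 would hold 1.64 and that of Sorbs2, which encodes a Z-disc adaptor protein, 0.941.

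FOG2 peaks were found at the gene of FOG2 itself, at Gata4 and at Tbx5. Zfpm2 (chromosome 15, 40655042 to 41104592) contained 7 summits, all inside the gene body, the strongest at 10.3-fold with 28 fragments (18.6 to 40.5) at 40979675 to 40980022. Gata4 had 3 summits, the strongest inside the gene at 7.66-fold with 13 fragments (6.92 to 22.2), at 63255886 to 63256309 on chromosome 14. Tbx5 had 3 summits, the strongest 22.8 kb outside the gene at 8.70-fold with 14 fragments (7.65 to 23.5), at 119907829 to 119908141 on chromosome 5. Genes of large territory often have a summit, with 53.1% in the largest decile of territory against 1.39% in the smallest. Zfpm2, Gata4 and Tbx5 were not among the 25 genes, described below, that held more summits than their territory would. Of the other cardiac GATA genes, named after their values were seen, Gata6 had 5 summits (strongest 8.02-fold, 13 fragments, 6.92 to 22.2) and Gata5 had 0. Ryr2, the calcium release channel of the sarcoplasmic reticulum, had the strongest peak of the 12 genes fixed in advance, at 17.6-fold with 44 fragments (32.0 to 59.1), 25.4 kb outside the gene at 12132005 to 12132516 on chromosome 13. Atp2a2, the calcium pump SERCA2, had a single summit 19.0 kb outside the gene, at 12.9-fold with 28 fragments (18.6 to 40.5), at 122520876 to 122521368 on chromosome 5.

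**Figure D1:**
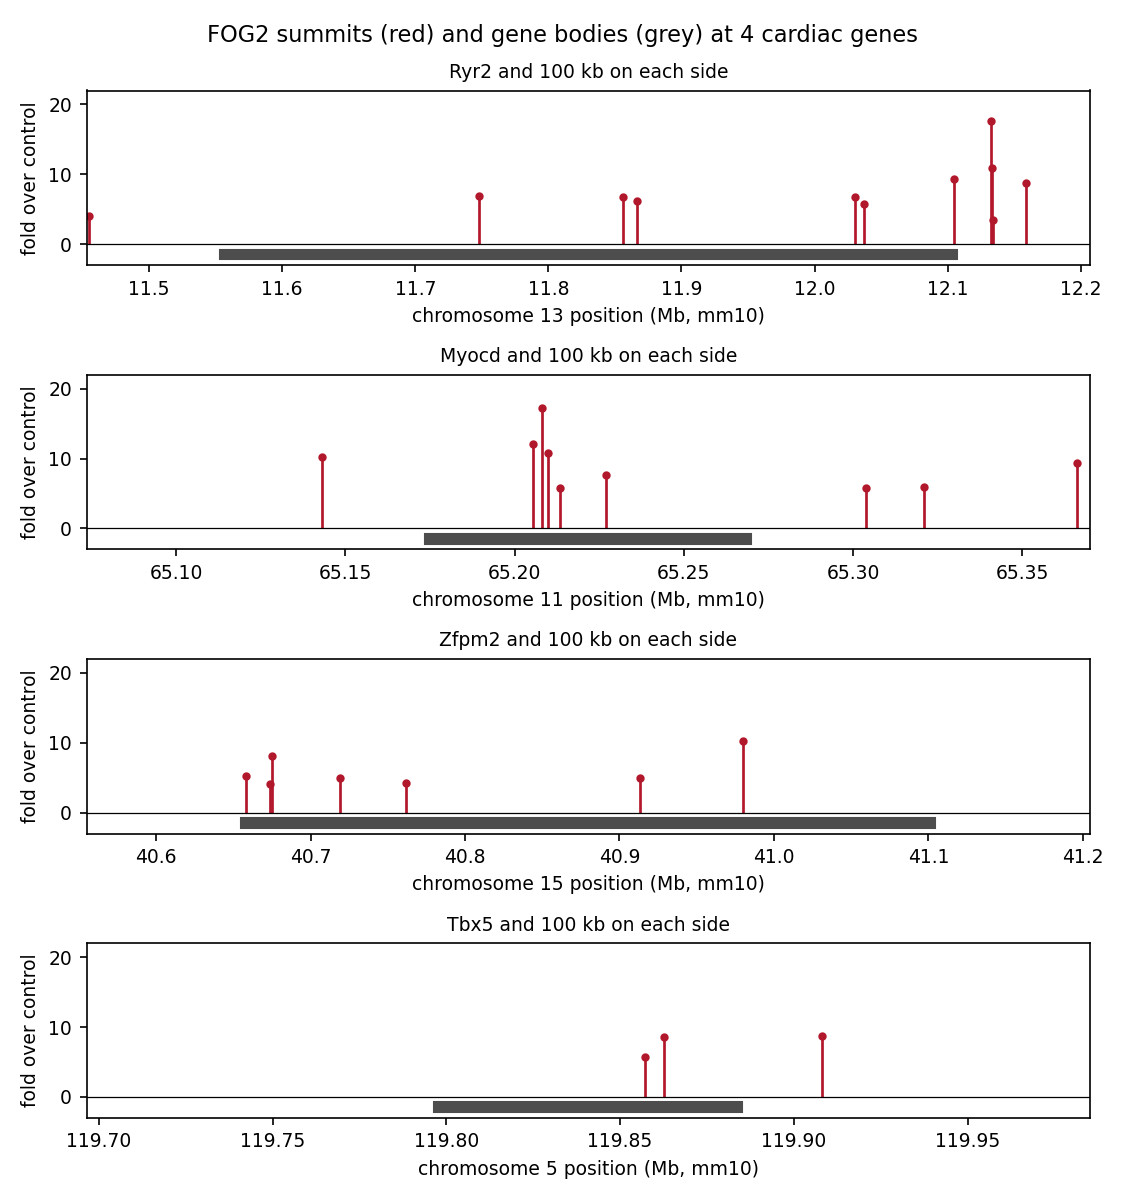
Maps of Ryr2, Myocd, Zfpm2 and Tbx5 with 100 kb on each side, with position in Mb (mm10) on the horizontal axis and fold over control on the vertical axis. Each red line is a summit and the grey bar is the gene body; the 7 Zfpm2 summits lie inside the gene, while the strongest Ryr2 summit (17.6-fold) lies outside it.

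The strongest peaks at Nppb, Kcnd3, Myh6 and Gja5 ranged from 5.80- to 7.97-fold, and Nppa and Hcn4 had none assigned. Nppb, a natriuretic peptide gene, had a summit 16.2 kb outside the gene at 7.97-fold (12 fragments, 6.20 to 21.0). It was also the nearest summit to the neighbouring Nppa, 31.2 kb away. Kcnd3, a potassium channel gene, had 2 summits (strongest 7.56-fold, 11 fragments). Myh6, the alpha myosin heavy chain gene, had 2 (strongest 6.88-fold, 10 fragments), and the connexin 40 gene Gja5 had 2 (strongest 5.80-fold, 9 fragments). The summit nearest to the pacemaker channel gene Hcn4 lay 12.4 kb away at 4.51-fold and was assigned to Rec114. The counting intervals of these summits overlapped, so no order among them was detectable at this depth.

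FOG2 summits were assigned to most genes of the contractile and calcium handling machinery. The random lists used here and below were matched on territory only, not on expression or open chromatin. The control was input, not a pulldown without tagged FOG2. A list above chance therefore does not separate selective FOG2 binding from a general preference of the pulldown for active genes. Of 31 sarcomere genes, 21 had a summit, against 4.15 in matched random lists (5.06 times the random mean, adjusted permutation p = 0.00105, from the smallest p the random lists can give). The highest folds were at Ankrd1 (26.5-fold, 74 fragments, 58.1 to 92.9), Tnni1 (22.9-fold), Pdlim5 (13.6-fold) and Cryab (11.6-fold). Of 18 calcium handling genes, 16 had a summit against 6.14 (2.61 times, adjusted permutation p = 0.00105). They were led by Cacnb2, a subunit of the L-type calcium channel (19.8-fold), Ryr2 (17.6-fold), Atp2a2 (12.9-fold) and Camk2d (11.2-fold). Energy metabolism genes with a summit numbered 7 of 20 against 2.40 (2.92 times, adjusted permutation p = 0.0107), led by Ppargc1a (20.3-fold), Esrrg (17.9-fold), the myoglobin gene Mb (11.3-fold) and Cox6a2 (10.9-fold). With only summits over 1 kb from a gene end, the list lost its call (adjusted permutation p = 0.509).

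Genes of cardiac transcription factors were also above chance. A summit was assigned to 22 of 30, against 9.62 in random lists (2.29 times, adjusted permutation p = 0.00105). The highest folds were at Nkx2-5 (22.1-fold, 23.9 kb outside the gene), Tbx3 (19.7-fold, 92.5 kb outside), Myocd (17.3-fold, inside) and Prdm16 (12.8-fold, inside). Myocd, which encodes a coactivator of SRF, had 8 summits. In the heart developmental signalling list, 15 of 24 genes had a summit against 7.01 (2.14 times, adjusted permutation p = 0.0042). The leading genes were Bmp7 (21.8-fold), Vegfa (19.9-fold), the neuregulin receptor gene Erbb4 (17.7-fold) and Tgfb2 (12.8-fold).

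Both chamber identity lists were above chance. The list names do not show in which chamber their genes were active at E12.5, since expression was not measured here. Of 14 ventricular identity genes, 9 had a summit against 3.21 (2.81 times, adjusted permutation p = 0.00252), led by Irx1 (12.6-fold), Fhl2 (12.4-fold), Myl3 (9.37-fold) and Myl2 (9.20-fold). Of 14 atrial identity genes, 8 had a summit against 2.77 (2.89 times, adjusted permutation p = 0.00472), led by Nr2f2 (20.5-fold), Bmp10 (12.49-fold), Tbx5 (8.70-fold) and Kcnj5 (7.22-fold). The atrial call was lost in the stronger 50% of peaks (adjusted permutation p = 0.0532). The difference between the chambers' lists was not tested. In each list, most genes with a summit also belonged to another list. Examples are Tbx5, Bmp10 and Kcnj5 among the atrial genes and Fhl2, Myl3 and Myl2 among the ventricular ones. Both calls are therefore not independent of the other lists, and the genes in no other list were not tested separately.

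Disease lists showed the same direction. These names likewise do not describe the state of the embryonic tissue, in which expression of the genes was not measured. Of 34 genes at loci associated with atrial fibrillation, 23 had a summit against 10.2 (2.26 times, adjusted permutation p = 0.00105). Those of highest fold were Sox5 (34.1-fold), Lrrc10 (22.5-fold), Nkx2-5 (22.1-fold) and Tbx3 (19.7-fold). Of these 34 genes, 22 also belonged to the transcription factor, sarcomere, calcium, ion channel or chamber lists. The other 12, separated after the result was seen, had 6 genes with a summit against 3.51 (permutation p = 0.152), which did not pass the threshold. Of 14 heart failure stress genes, 7 had a summit against 2.05 (3.42 times, adjusted permutation p = 0.00472), led by Ankrd1 (26.5-fold), Fhl2 (12.4-fold), Nppb (7.97-fold) and Myh7 (7.14-fold). Of these 14 genes, 8 also belonged to another list, among them 5 of the 7 with a summit. The other 6, separated after the result was seen, had 2 genes with a summit against 1.11 (permutation p = 0.601). The call on the whole list was lost under 3 alternatives, with adjusted permutation p between 0.0836 and 0.176.

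**Figure D2:**
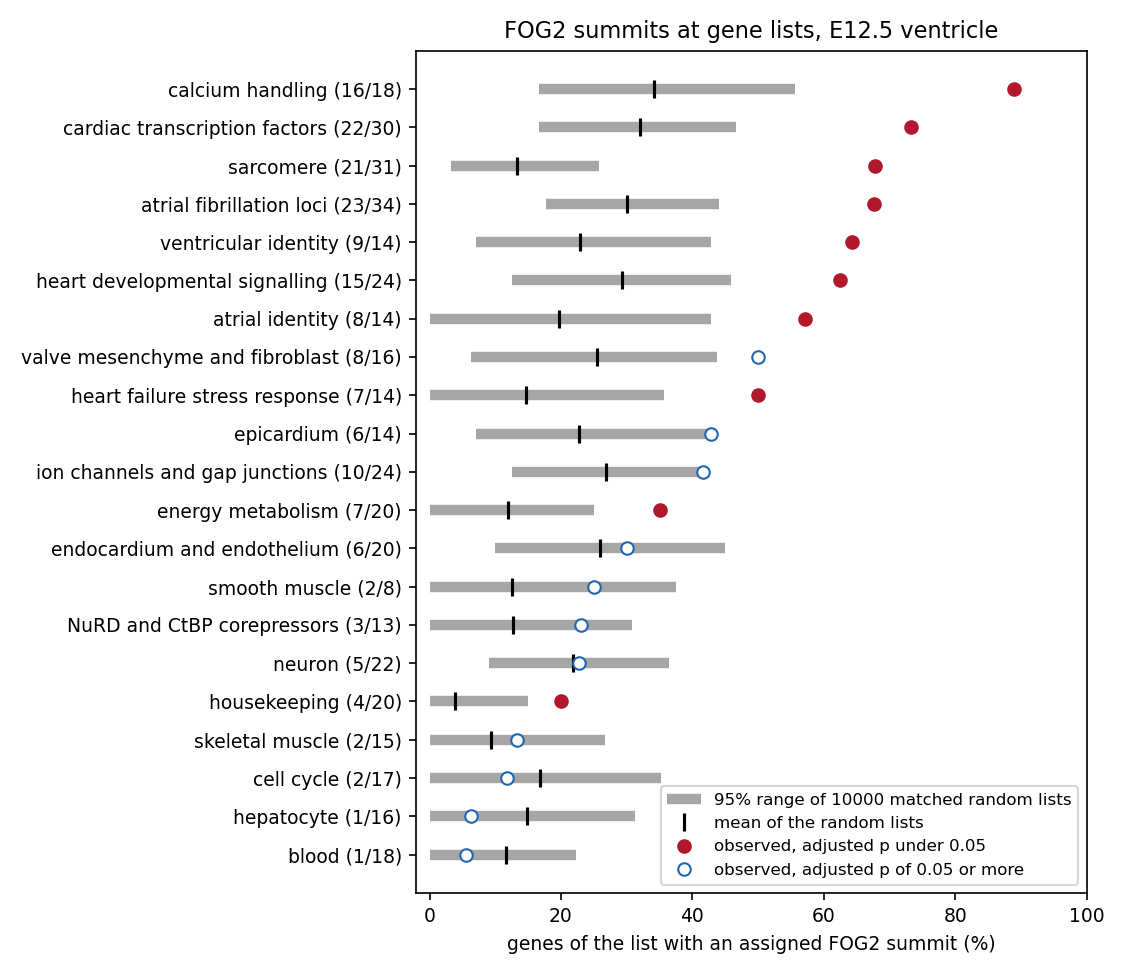
Share of each list's genes with an assigned FOG2 summit (horizontal axis, percent), with counts beside the list names. Grey bars give the 95% range and black ticks the mean of 10000 random lists matched on territory; filled red points mark the 10 lists with an adjusted permutation p under 0.05, and calcium handling stands highest at 16 of 18 genes.

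Lists of other cardiac cell types and of ion channels did not pass the threshold. Ion channel and gap junction genes had 10 of 24 with a summit against 6.44 (1.55 times, adjusted permutation p = 0.201), led by Kcnk3 (22.7-fold), Scn10a (14.0-fold), Kcnd2 (12.4-fold) and Ank2 (8.12-fold). For the valve mesenchyme and fibroblast list the count was 8 of 16 against 4.08 (adjusted permutation p = 0.0855), with Pdgfrb (14.5-fold), Has2 (7.67-fold), Sox9 (6.22-fold) and Pdgfra (5.77-fold) highest. Epicardial genes had 6 of 14 against 3.18 (adjusted permutation p = 0.176), with Tbx18 (15.8-fold), Sema3d (9.92-fold), Wt1 (5.66-fold) and Bnc1 (5.47-fold) highest. Endocardial and endothelial genes had 6 of 20 against 5.18 (adjusted permutation p = 0.892), with Erg (17.6-fold), Npr3 (8.64-fold), Ets1 (7.66-fold) and Tek (7.54-fold) highest. Smooth muscle genes had 2 of 8 against 0.998 (adjusted permutation p = 0.639), namely Myocd and Myh11 (9.92-fold).

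No list of a cell type outside the heart passed the threshold, and neither did the cell cycle or corepressor lists. For the blood, hepatocyte, skeletal muscle, cell cycle and corepressor lists, the 95% range of the random lists reached down to 0 genes. A count below chance could therefore not be detected for these lists. Blood genes had 1 of 18 with a summit against 2.102 (adjusted permutation p = 0.767), which was Runx1 (16.2-fold). Hepatocyte genes had 1 of 16 against 2.38 (adjusted permutation p = 0.639), which was Tat (5.67-fold). Neuronal genes had 5 of 22 against 4.81 (adjusted permutation p of 1), with Syt1 (11.2-fold), Dlx2 (8.70-fold) and Neurog1 (6.30-fold) among the highest. Skeletal muscle genes had 2 of 15 against 1.41 (adjusted permutation p = 0.892), namely the embryonic myosin gene Myh3 (29.8-fold) and Chrna1 (6.77-fold). Cell cycle genes had 2 of 17 against 2.85 (adjusted permutation p = 0.892), namely Ccnd2 (16.4-fold) and Myc (7.70-fold). Genes of the NuRD and CtBP corepressors, to which FOG proteins are known to bind, had 3 of 13 against 1.64 (adjusted permutation p = 0.639), namely Mta1 (19.5-fold), Chd4 (10.1-fold) and Ctbp2 (7.31-fold).

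The housekeeping list was above chance, with 4 of 20 genes against 0.780 (5.13 times, adjusted permutation p = 0.0202). The genes were Pgk1 (157.8-fold), Hprt (17.0-fold), Eef1a1 (8.49-fold) and Actb (7.54-fold). Without the peaks at Pgk1, Larp7, Hprt and the 3 widest intervals, the call was lost (2.57 times, adjusted permutation p = 0.595). Across the genome 2938 of 21631 protein-coding genes (13.6%) had a summit, and 23.7% of summits had no gene within 100 kb. Assignment to the nearest gene does not show which gene a site acts on.

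Summits lay inside gene bodies more often than in random placements. Elsewhere in a gene body, over 1 kb from its ends, lay 2721 summits (44.1%, Wilson 95% interval 42.9 to 45.4, jackknife SE 1.12) against 38.7% at random (1.14 times, permutation p = 0.002). Outside gene bodies lay 3246 summits (52.6%, 51.4 to 53.9, SE 1.27) against 58.3% (0.903 times, permutation p = 0.002). Within 1 kb of a gene end lay 199 summits (3.23%, 2.81 to 3.70, SE 0.312), against 3.02% at random (1.07 times, permutation p = 0.388). With gene ends widened to 5 kb the last ratio was 0.882 (permutation p = 0.002), and with genes of any biotype it was 1.14 (permutation p = 0.00799). The random placements left out neither assembly gaps nor blacklisted or unmappable sequence, where no peak can be listed. How far this moved the ratios was not tested.

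Fold differed little between these classes. Summits within 1 kb of a gene end had a median fold of 6.32 and the others 6.39, a difference of -0.0751 (95% bootstrap interval -0.516 to 0.186, adjusted permutation p = 0.743). Summits elsewhere in a gene body had a median of 6.37 against 6.57 outside gene bodies, a difference of -0.201 (-0.429 to 0.0094, adjusted permutation p = 0.0484). That interval includes 0, and the call was lost under 3 alternatives.

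Peak density was lowest on the X chromosome. It carried 99 peaks, or 0.580 per Mb (95% Poisson interval 0.471 to 0.706), while the 19 autosomes ranged from 1.82 per Mb on chromosome 7 to 3.20 per Mb on chromosome 10. The median fold was 6.38 on the X chromosome, within the range over autosomes, and both Pgk1 and Hprt lie on it.

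**Figure D3:**
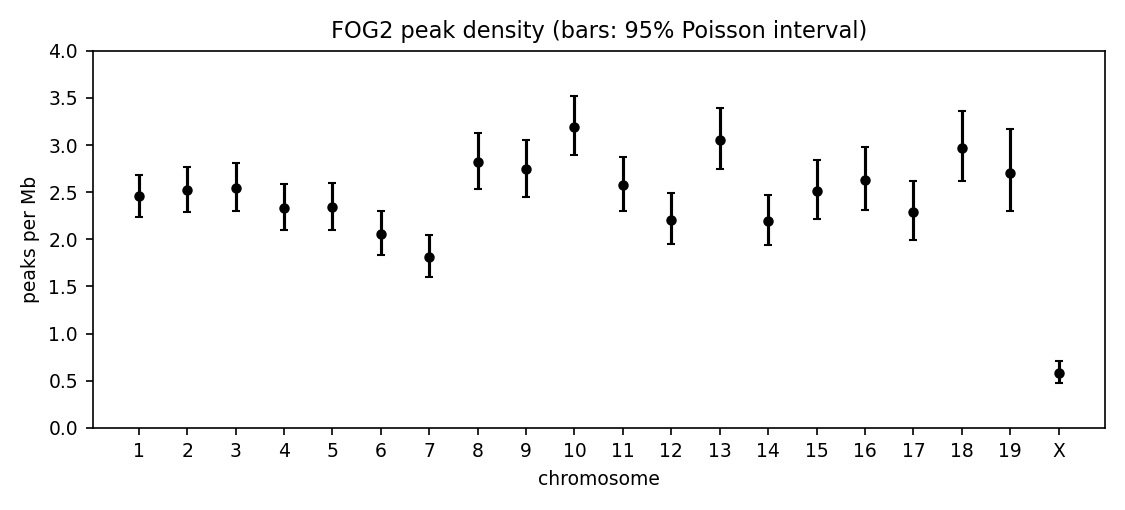
FOG2 peaks per Mb (vertical axis) on each chromosome (horizontal axis), as points with 95% Poisson intervals. The X chromosome, at 0.580 per Mb, lies below all 19 autosomes.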

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

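Leaving out the peaks at Pgk1, Larp7, Hprt and the 3 widest intervals, recovered fragments as the strength, and the nearest gene end were chosen only after the results were seen. The excess of summits in gene bodies and the deficit outside them kept their direction and passed the threshold in all 6 alternatives run. Of the 10 lists above chance, 6 were called in all 8 alternatives, namely ventricular identity, cardiac transcription factors, sarcomere, calcium handling, atrial fibrillation loci and heart developmental signalling. The number of lists called ranged from 8 to 12. Heart failure stress response was lost in 3 alternatives, atrial identity and energy metabolism in 1 each, and housekeeping in 5. Unmatched random lists added epicardium, ion channels and valve mesenchyme, and assignment within 10 kb of gene bodies added valve mesenchyme. Peaks with a −log10 q of at least 5 numbered 4097. The ratio at gene ends was 0.882 at 5 kb, below 1, and 1.14, past the threshold, with genes of any biotype. The difference in median fold at gene ends was 0.165 in the stronger 50% of peaks, opposite in sign. The difference between gene bodies and the regions outside them no longer passed the threshold without the peaks named above (-0.196), as −log10 q (-0.0852) or as recovered fragments (0). Among lists that had not passed the threshold, ratios crossed 1 for epicardium at a −log10 q of at least 5 (0.834), and for valve mesenchyme (0.859), neuron (0.674) and cell cycle (1.19) in the stronger 50% of peaks. Within 10 kb of gene bodies they crossed for neuron (0.951) and cell cycle (1.55), and within 20 kb for neuron (0.866) and cell cycle (1.59). They also crossed for neuron over 1 kb from gene ends (0.855) and with the nearest gene end (0.901), and for skeletal muscle without matching (0.984). The cause of these changes was not tested. For the 85 named genes with a summit, 460 recomputed summit counts stayed within 1.5 times the original count and 135 did not. Motif alternatives and placement matched on GC content were not run, since no sequence was used here. No paired analysis was possible because the replicates were pooled, and for the same reason no replicate could be left out. Depth limits single peaks, with 39.4% of summits resting on 10 or fewer fragments.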

Other observations

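The tests of genes with dense summits, of a foreign sequence at Larp7, of extra copies at the widest peaks, of gene density on chromosome 12, of both X chromosome factors together and of the housekeeping list without Eef1a1 and Actb were chosen only after the results were seen. Beyond the lists, 25 protein-coding genes held more summits than their territory would at the density of their chromosome (exact Poisson test, one-sided, Benjamini-Hochberg adjusted p under 0.05 over 21631 genes). The genes were picked and tested on the same summits, and the test treats summits as independent although they lie close together, so its p-values are too small. Jup, the gene of the junction protein plakoglobin, held 8 summits within or near 29.0 kb of gene body on chromosome 11, against 0.106 expected, with a highest fold of 10.1. Csrp3 held 4 against 0.0527, Ldb3 held 4 against 0.145, Tnni3 held 2 against 0.00909 and the myoglobin gene Mb held 4 against 0.168. The actin-associated genes Mical2 (8 against 0.307, up to 23.5-fold), Sorbs2 (10 against 1.12) and Palld (8 against 1.15) were also among them.

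Also among the 25, Myocd held 8 summits against 0.518 expected and Meis1 held 7 against 0.873. Tbx19 held 5 against 0.319 (up to 24.8-fold) and Bach2 held 8 against 1.06. S1pr1, a sphingosine-1-phosphate receptor gene of 4.62 kb, held 7 summits against 0.486, and the receptor genes Ror1 and Igf2r held 10 against 0.981 and 6 against 0.286. In all, 7 of the 25 genes (28.0%) were in a list, against 1.63% of all protein-coding genes, a comparison not matched on territory. Larp7, with 7 summits, was also among the 25.

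A few loci stood apart in height or width, and all 8 peaks in or within 1 kb of Pgk1 and Larp7 were at least 36.3-fold over control. The widest peak (5602 bp, chromosome 6, 113071623 to 113077224) lay in Gt(ROSA)26Sor, the locus that carries the BirA ligase per the labels' protocols, and the next widest (4495 and 3886 bp) lay in Hprt and 3.20 kb from Phf6. Extra copies in the tissue genome would raise the input as well, but the control level they need was 34.3 times the level found at Pgk1 and Larp7 (23.4 against 0.683) and 7.20 times that at the 3 widest peaks, which argues against them. Sequence foreign to the tissue genome in the pulldown libraries, such as a DNA construct, may be a source, since Pgk1 sequence is common in selection cassettes. The 2 Pgk1 peaks lay across the 2 ends of the gene body, at 157.8- and 42.8-fold, with none listed between them. The second spanned X 106203559 to 106204217. Why the Pgk1 peaks lay only at the ends was not tested. The count of peaks within 50 kb outside the Larp7 body at 36.3-fold or more was 0, but only 1 peak lay there (13.9-fold), so foreign sequence cannot be told apart from occupancy, and no biological explanation was tested.

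The X chromosome had 0.580 peaks per Mb against 2.50 on autosomes. If all embryos were male, X copies would be fewer, but thinning the autosomal summits to a share of 0.5 left 69.8% of them past the p of the weakest listed peak, or 1.74 per Mb, above the X interval (0.471 to 0.706), which argues against copy number alone. Gene density alone is argued against too, since chromosome 12, with the same 5.66 protein-coding genes per Mb as the X, had 2.21 peaks per Mb (1.95 to 2.49), and the X had 10.2 peaks per 100 genes against 13.0 on the lowest autosome. Both factors together would need a thinned density on chromosome 12 close to that of the X, and it was 1.44 per Mb (1.23 to 1.67). Per 100 genes, however, the lowest autosome, chromosome 7, fell to 9.02 peaks after the same thinning, below the X. These comparisons differ, so they do not settle whether both factors together could account for the X density. Repeat content, mappability and the sex of the embryos were not examined, and no biological explanation was tested.

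The housekeeping call rested on 4 genes. Without the Pgk1 and Hprt peaks the adjusted permutation p was 0.597, and without the Eef1a1 and Actb peaks, it was 0.597 as well. Each removal left 2 of 20 genes with a summit and ended the call, so the test does not single out Pgk1 and Hprt, and their part in it cannot be told apart from that of the others.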
